A study of Mus musculus with 22 samples.

How the data were processed

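Array comparative genomic hybridisation was used to measure DNA copy number in spheres grown from TH-MYCN hemizygous mice. TH-MYCN mice carry the human MYCN oncogene under a tyrosine hydroxylase promoter and develop neuroblastoma, often in the superior mesenteric ganglion. Per the labels, the series holds 22 arrays in 3 groups: spheres from the ganglion of embryos at day 13.5 (E13.5 spheres, 6 arrays), spheres from the ganglion at 3 weeks of age (3-week spheres, 8 arrays) and primary spheres from tumours of mice 10 to 15 weeks old (tumour spheres, 8 arrays). The E13.5 spheres had been passaged between 2 and 4 times and the 3-week spheres 2 times, whereas the tumour spheres are described as primary. Group, replicate number and passage number came from the labels alone, and arrays are named here by group and replicate number. The labels call the samples biological replicates. They do not state whether each reference came from the same animal as its spheres.

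Sphere DNA was labelled with Cy5 and reference DNA with Cy3, per the labels, so every ratio is sphere over reference. The reference was whole head for the E13.5 spheres and spleen for the 3-week and tumour spheres. No array had its dyes swapped, so a dye effect stays in every ratio against the reference and drops out of a difference between groups only where it is the same in both. Per the file headers, the scanner files were written by Agilent Feature Extraction 11.0.1.1 with the protocol CGH_1100_Jul11, on probes placed on the mouse build mm9. The LogRatio column is log10 of red over green and was deposited by the authors as that software computed it, after its own background subtraction and dye normalisation. The software's intensity columns, deposited in the same files, hold the processed signal and the median foreground and background intensity of each channel. The authors also deposited a table of log2 ratios for the whole series with scale, centring and direction unstated. Set against each array's scanner values, its 22 columns each correlated best with their own array (r from 0.934 to 0.9999), with slopes from 0.871 to 0.9997 and column medians from -0.01 to 0.05. Its scale and direction were therefore settled by that comparison, while the authors' own centring stays unknown.

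Here the LogRatio was multiplied by log2 of 10, control spots and spots with an outlier flag were dropped (0.0654 to 0.246% of the spots of an array), spots of one probe were averaged, and each array was centred on the median of its autosomal probes. No loess or quantile step was used, since real copy number changes carry signal on many probes. Each array had 174305 probe spots for 170305 probes, of which 161460 were autosomal, 8723 on X and 122 on Y, at a median distance of 11.3 kb between neighbouring autosomal probes. On all arrays 168932 probes were well above background in both channels. The number of arrays limits the precision. No pair of arrays correlated above 0.782, so none was counted as a repeat of another.

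Noise was taken as the median absolute difference between neighbouring probes, scaled to an SD of a single probe. Segments were found per array and chromosome by penalised least squares, with a penalty of 4 times the noise variance times the natural log of the number of probes. A segment was called when it held at least 10 probes and its mean was at least 0.2 in size, and was called focal up to 3 Mb. On simulated arrays of 8000 probes, segments of 20 probes at a log2 of 0.3 were recovered in 100% of runs at a noise SD of 0.1, in 80% at 0.15 and in 0% at 0.25. Segments of 60 probes were recovered in 95% at a noise SD of 0.25, and no false segment was called. The simulated noise was independent between probes, so these runs do not measure segments called from a profile that arrays share along the genome. A gain from 2 to 3 copies in every cell would give a log2 ratio of 0.58 and a loss of 1 of 2 copies -1.00.

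The design fixed before the data were examined called for tests of genes. The files place probes on mm9, and the gene table used here (GRCm38) has another build, so coordinates were not carried between builds. Windows of 1 Mb on mm9 with at least 10 probes (2531 windows on the autosomes and X, median of 70 probes) took the place of genes, each window taking the median of its probes. Regions are therefore named by position, and gene content at single positions was not analysed here. The rule for named genes was applied to windows: up to 10 with the highest and up to 10 with the lowest value among those called, at most 1 per 10 Mb and at most 3 per chromosome and direction. It was also applied to called focal segments, taking the 5 largest of each group and every one shared by at least 2 arrays, and to each chromosome past 0.2 in an array or past an exact test. Of the windows and chromosomes the rule takes, the Results print only some, chosen after their values were seen, and other regions were chosen after their values were seen too. The 12 gene lists fixed beforehand could be placed only by chromosome, so each member took the median of its chromosome. The tests of antigen receptor loci and the corrections for GC content need positions or sequence on mm9 and were not run.

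Windows were tested with limma (lmFit and eBayes) on all 22 arrays in one fit of the 3 groups, which share one estimate of the spread. A window was called at a Benjamini-Hochberg adjusted p under 0.05 and a mean or difference of at least 0.1 in size. On 200 simulated windows with a shift of 0.2 among 2531, the fit recovered 100% for tumour spheres against the reference, 98% for tumour minus 3-week spheres and 97% for tumour minus E13.5 spheres. With a shift of 0.15 it recovered 99%, 98% and 96%, with 0, 0 and 3 false calls. Chromosome medians (19 autosomes and X) were tested against 0 with exact two-sided sign-flip permutation tests. Differences between groups in chromosome medians, in the percent of autosomal probes within called segments and in noise were tested with exact two-sided permutation tests. Each family was adjusted by Benjamini-Hochberg. The smallest p these designs allow is 0.031 for sign flips of 6 arrays, 0.0078 for 8 arrays, 0.00016 for 8 against 8 and 0.00033 for 8 against 6. A test against the reference leaves out the spread of the reference DNA.

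The arrays lay on 6 slides, each holding arrays of 1 group, and were scanned in 2 sessions. The first session held 4 of the E13.5 arrays, and the second held the other 2 of them and all arrays of both other groups. Slide was fitted as a random block and session as a fixed block, and the later session was also analysed alone. Further alternatives were normexp background correction of the median signals (offset 50), the authors' table, another centring, array quality weights, fits of only the groups compared, probes well above background on all arrays, other sizes and penalties for calls, the replicate number as a block, and leaving out each array in turn. Several were added only after the data were seen: the blocks and subsets by scan session, leaving out the 2 noisiest arrays or both arrays with a lower chromosome 3, removal of a trend on probe density, array-specific ratios (an array minus the median of the other arrays of its group), the authors' table for segments and chromosomes, shared focal segments with each array left out, tests of X within arrays with or without a Y signal in the spheres, and all splits of the later session's arrays. For each pair of groups, the difference in each channel was regressed on the difference in the ratio over 2383 autosomal windows, also within the later session, a step added after the data were seen. The ratio holds both channels, so the 2 slopes of a pair differ by about 1 by construction. Single channels were compared over 1 interval after centring each probe on its own mean over the 22 arrays, a step added after a first version without it. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, numba 0.67.0, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.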

Results

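DNA copy number was measured on 22 arrays of spheres from TH-MYCN mice, a transgenic model of neuroblastoma. Spheres are floating clusters of cells grown in culture. They came from the superior mesenteric ganglion, a sympathetic ganglion in the abdomen, of embryos at day 13.5 (n = 6) and of mice at 3 weeks of age (n = 8), and from tumours (n = 8). Each array set sphere DNA against reference DNA of embryo head or spleen, and values are log2 ratios of sphere over reference on 170305 probes. Positions are on the mouse build mm9. The noise of a single probe was 0.113 ± 0.00727 (SD, n = 8) in tumour arrays, 0.158 ± 0.0547 (SD, n = 8) in 3-week arrays and 0.147 ± 0.0267 (SD, n = 6) in E13.5 arrays. Tumour arrays were quieter than 3-week arrays by a mean difference of -0.0443 (exact permutation test, p = 0.00093, adjusted p = 0.0015) and than E13.5 arrays by -0.0331 (p = 0.001, adjusted p = 0.0015). The noisiest arrays were 3-week 7 (0.231) and 3-week 8 (0.258), and at a noise of 0.25 simulated segments of 20 probes at 0.3 were recovered in 0% of runs.

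The design sets spheres from the ganglion at both ages against spheres from tumours. The largest shift of a chromosome median lay on chromosome 3 of tumour 5, whose median was -0.49 against -0.01 to 0.01 in the other 7 tumour arrays. It formed a single segment from 3000029 to 159598830 with 9463 probes and a mean of -0.49, the size that loss of 1 of 2 copies in 57.6% of cells would give. Tumour 2 carried a gain on chromosome 10 from 25312348 to 60000860, a stretch of 34.7 Mb and 2185 probes, with a mean of 0.32, the size that 1 extra copy in 50.4% of cells would give. Chromosome 18, whose distal end is known as the site of the transgene, had a median of -0.18 in tumour 7 against -0.01 to 0.01 in the other tumour arrays. Chromosome 3 was also lower in 1 sphere line of embryonic origin, E13.5 2, with a median of -0.19 against 0.03 to 0.04 in the other E13.5 arrays. Against the median of those arrays it formed a single segment from 3000029 to 159598830 with a mean of -0.22. No array other than tumour 5 had a chromosome median past 0.2 in size.

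**Figure D1:**
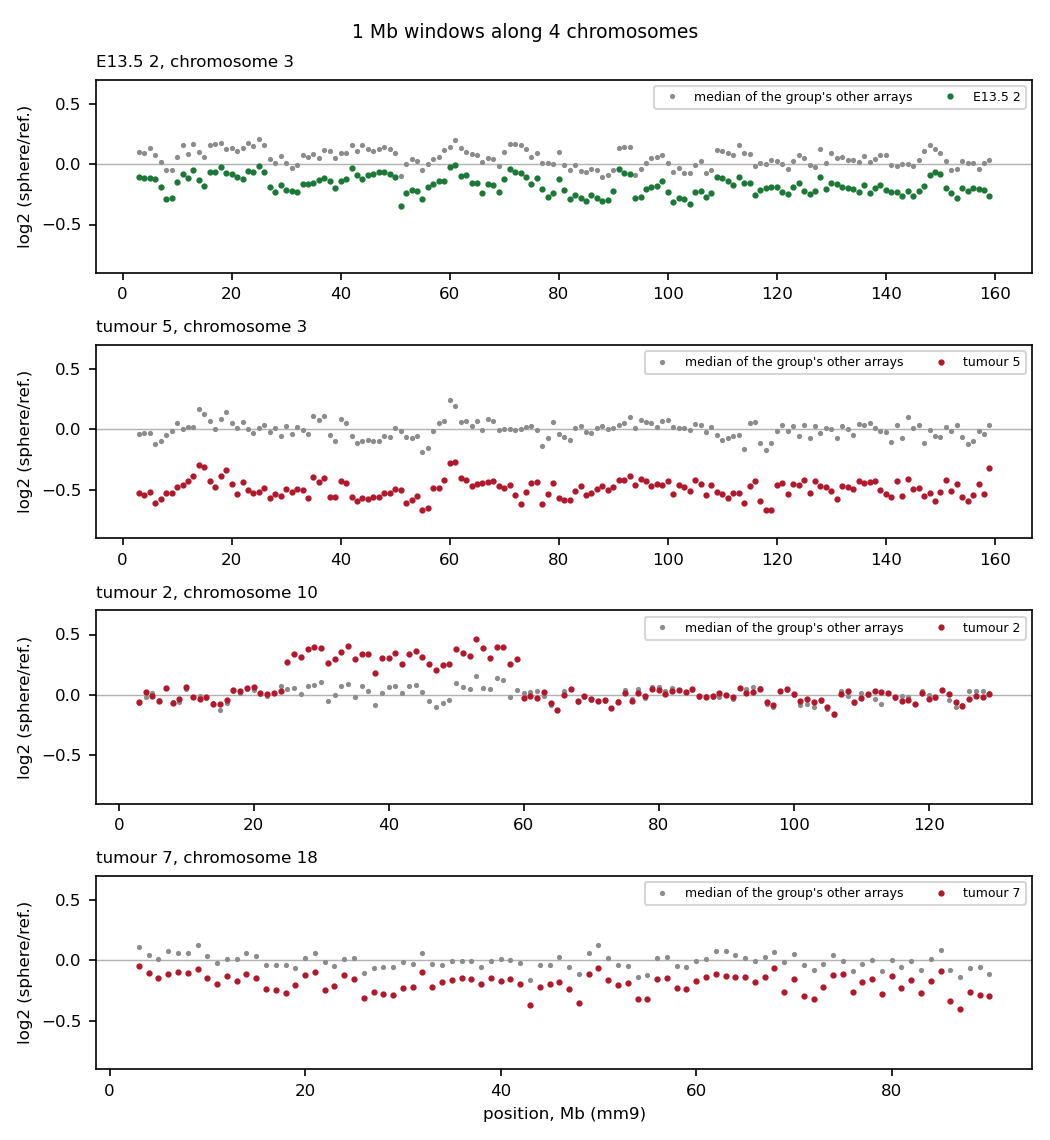
Log2 ratio of sphere over reference in windows of 1 Mb (y axis) against position on mm9 in Mb (x axis) for 4 chromosomes, each in the array named above its panel (colour) and as the median of the other arrays of its group (grey). Tumour 5 lies near -0.49 along chromosome 3, E13.5 2 lies below its group along chromosome 3 (median -0.19), tumour 2 is raised over 34.7 Mb of chromosome 10 (mean 0.32), and tumour 7 lies below its group along chromosome 18 (median -0.18).

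Segments called from 0.2 held 1.63 ± 2.16% (SD, n = 8) of autosomal probes in tumour spheres, 0.340 ± 0.579% (SD, n = 8) in 3-week spheres and 0.829 ± 1.53% (SD, n = 6) in E13.5 spheres. The highest shares were 6.77% in tumour 5, of which 6.28% were losses, 3.92% in E13.5 2 and 1.72% in 3-week 3. E13.5 5, 3-week 7 and 3-week 8 had no called segment. Tumour spheres did not differ from 3-week spheres by more than the spread between arrays (difference 1.29 percentage points, exact permutation test, p = 0.051, adjusted p = 0.15), nor from E13.5 spheres (0.797, adjusted p = 0.54). The 3-week minus E13.5 difference was -0.489 (adjusted p = 0.54), and it turned to 0.129 without E13.5 2 and to 0.292 within the later scan session. Tumour minus 3-week was 1.48 without 3-week 3 and then passed (adjusted p = 0.031), and it was 0.55 without tumour 5. Tumour minus E13.5 was 0.0616 without tumour 5 and 1.41 without E13.5 2. With segments called from 0.1 the shares were 13.8 ± 5.77% in tumour, 20.4 ± 11.4% in 3-week and 23.2 ± 12.7% in E13.5 spheres, and after normexp correction 1.66 ± 2.61%, 3.86 ± 2.26% and 1.07 ± 1.16%. The tumour minus 3-week difference turned to -6.53 with segments called from 0.1 and to -2.20 after normexp correction, and it passed with segments called from 0.3 (0.918, adjusted p = 0.021) and in the authors' table (1.45, adjusted p = 0.00047). With array-specific ratios, which take out what most arrays of a group share, tumour 5 held 5.86%, E13.5 2 5.88% and 3-week 3 0%. Tumour 2 then held 1.35%, while tumours 3 and 6, at 1.60% and 0.987% before, held 0.026% and 0.016%.

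**Figure D2:**
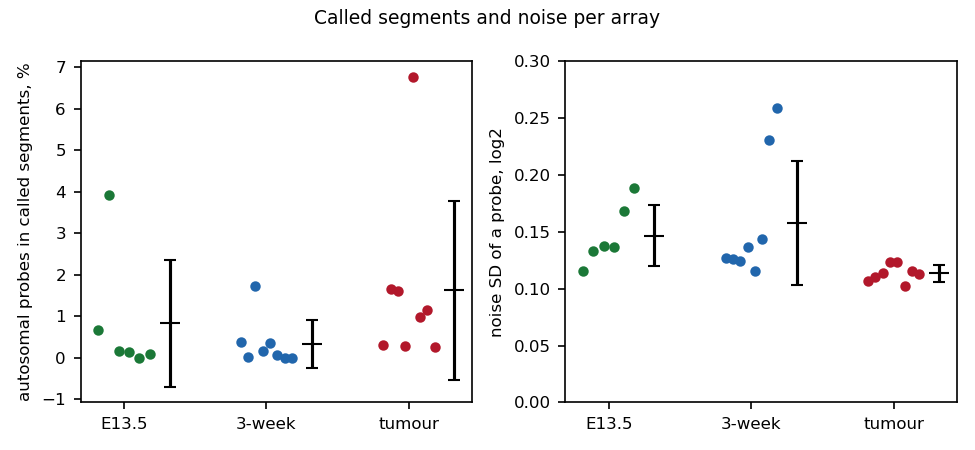
Percent of autosomal probes in called segments (left) and noise SD of a probe in log2 units (right) for each array of the 3 groups, with the mean and SD beside the points. Tumour 5 (6.77%), E13.5 2 (3.92%) and 3-week 3 (1.72%) stand above the other arrays of their groups, and the tumour arrays have the lowest mean noise (0.113).

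Focal segments of up to 3 Mb numbered 115 over the 8 tumour arrays, 26 over the 3-week arrays and 25 over the E13.5 arrays. Tumour arrays had the lowest mean noise (0.113, against 0.158 in 3-week and 0.147 in E13.5 arrays). The penalty for a segment grows with the noise, so the counts do not compare the groups evenly. The noisiest arrays, 3-week 7 and 3-week 8, had none on the autosomes. They were spread unevenly: on the autosomes tumours 3 and 6 held 27 and 25, 3-week 3 held 8, and E13.5 1 and E13.5 2 held 9 each. The 5 largest in tumours lay in 2 arrays. Tumour 6 had a gain of 1.06 on chromosome 13 from 80695376 to 81186771 (26 probes). Tumour 8 had gains of 0.88 on chromosome 16 from 5538529 to 6947712 (120 probes), 0.80 on chromosome 11 from 118028703 to 118377030 (36 probes) and 0.73 on chromosome 16 from 41615995 to 41803372 (20 probes), and a loss of -0.65 on chromosome 4 from 111900689 to 112036604 (11 probes). A gain of 2 to 3 copies in every cell would give 0.58. The largest in E13.5 spheres was a gain of 0.46 on chromosome 6 from 64042736 to 64386912 in E13.5 2 (36 probes). E13.5 1 had a loss of -0.36 on chromosome 4 from 112964274 to 113251939 (11 probes), E13.5 6 a loss of -0.35 on chromosome 12 from 29574586 to 30142313 (22 probes), E13.5 2 a loss of -0.32 on chromosome 4 from 111906561 to 112260102 (23 probes) and E13.5 1 a gain of 0.31 on chromosome 1 from 45347912 to 45555881 (24 probes). In 3-week spheres the largest were losses on chromosome 4 between 111953767 and 112232031, from -0.66 in 3-week 1 to -0.54 in 3-week 2, and a loss of -0.41 on chromosome 12 from 114670169 to 115207864 in 3-week 4 (43 probes).

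At least 2 arrays of a group shared a focal segment at 22 places in tumour spheres and at 4 in each other group. The count was 14 without tumour 3, and in 3-week spheres 2 without 3-week 5. All 8 tumours had a higher segment on chromosome 6 between 41025051 and 41779578 (tumour mean 0.24 ± 0.024, SD, n = 8), where 3-week spheres lay at 0.20 ± 0.018 (SD, n = 8) and E13.5 spheres at 0.13 ± 0.013 (SD, n = 6). All 8 also had one on chromosome 7 between 110917151 and 111324088 (tumours 0.30 ± 0.044, 3-week spheres 0.25 ± 0.025, E13.5 spheres 0.12 ± 0.012). A loss on chromosome 7 between 69099752 and 69850071 was called in 6 tumours, with group means of -0.27 ± 0.046 in tumours, -0.03 ± 0.021 in 3-week spheres and 0.02 ± 0.030 in E13.5 spheres. Chromosome 4 near 112 Mb varied between arrays of every group: over 111900689 to 112036604 the means were -0.62 ± 0.17 in tumours, -0.14 ± 0.18 in 3-week spheres and -0.16 ± 0.093 in E13.5 spheres. Over 112915864 to 113197520 on the same chromosome they were -0.32 ± 0.21, -0.08 ± 0.088 and -0.11 ± 0.14. A gain on chromosome 5 between 12361948 and 13550580 was called in 5 of the E13.5 arrays, as a focal segment in E13.5 2 and E13.5 6 and within segments longer than 3 Mb in E13.5 1, E13.5 3 and E13.5 4 (group mean 0.24 ± 0.053, against 0.09 ± 0.034 in 3-week spheres and -0.02 ± 0.034 in tumours). In 3-week spheres the loss shared most widely lay on chromosome 12 between 114670169 and 115126863, called in 5 arrays, with a mean of -0.28 ± 0.085 against -0.02 ± 0.058 in tumours and 0.06 ± 0.038 in E13.5 spheres. These counts come from no test, and the lower noise of tumour arrays makes a call easier there.

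The other places shared in 3-week spheres were a loss on chromosome 4 between 111972661 and 112091879 in 4 arrays (group mean -0.42 ± 0.36) and gains in 2 arrays each on chromosome 5 between 68965579 and 71451876 (0.17 ± 0.033) and on chromosome 7 between 111168299 and 111507023 (0.28 ± 0.022). In E13.5 spheres 3 arrays each shared gains on chromosome 15 between 3114799 and 3951677 (0.17 ± 0.050) and on chromosome 13 between 15569192 and 16316116 (0.18 ± 0.045), and 2 shared a loss on chromosome 4 between 112964274 and 113251939 (-0.15 ± 0.14). In tumours a higher segment on chromosome 3 between 60300191 and 61595123 was called in 5 arrays (group mean 0.18 ± 0.17) and a lower one on chromosome 1 between 14240952 and 14789565 in 4 (-0.25 ± 0.056). Called in 3 tumours were lower segments on chromosome 5 between 15241273 and 15498883 (-0.25) and chromosome 13 between 116174443 and 117620308 (-0.22), and higher ones on chromosome 4 between 144479820 and 146804371 (0.21), also within a longer segment of tumour 5, and chromosome 17 between 40586738 and 41013885 (0.21). Lower segments in 2 tumours lay on chromosome 18 between 42751339 and 44042926 (-0.18), chromosome 1 between 18889432 and 20484249 (-0.16) and chromosome 11 between 71032791 and 71582858 (-0.10). Others lay on chromosome 10 between 105609074 and 107166534 (-0.17), chromosome 7 between 100724800 and 103311564 (-0.17) and chromosome 9 between 117076170 and 117609394 (-0.17). Higher segments in 2 tumours lay on chromosome 2 between 150316100 and 151198351 (0.18), chromosome 3 between 99953338 and 100358444 (0.15), chromosome 15 between 61887685 and 62171249 (0.19) and chromosome 16 between 98131539 and 98280304 (0.19). A higher segment on chromosome 14 between 41624528 and 44579789 (0.22) was called in 5 tumours, as a focal one in tumours 1 and 3 and within longer ones in tumours 2, 5 and 6. Several of these places lay at a similar level in another group, so a call does not make them particular to 1 group. E13.5 spheres lay at 0.17 on chromosome 5 from 68965579 and at -0.11 on chromosome 11 from 71032791. On chromosome 4 from 144479820 and on chromosome 14, 3-week spheres lay at 0.22 and 0.21. Others lay further apart, such as chromosome 7 from 100724800 (3-week spheres -0.06, E13.5 spheres 0.01).

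**Figure D3:**
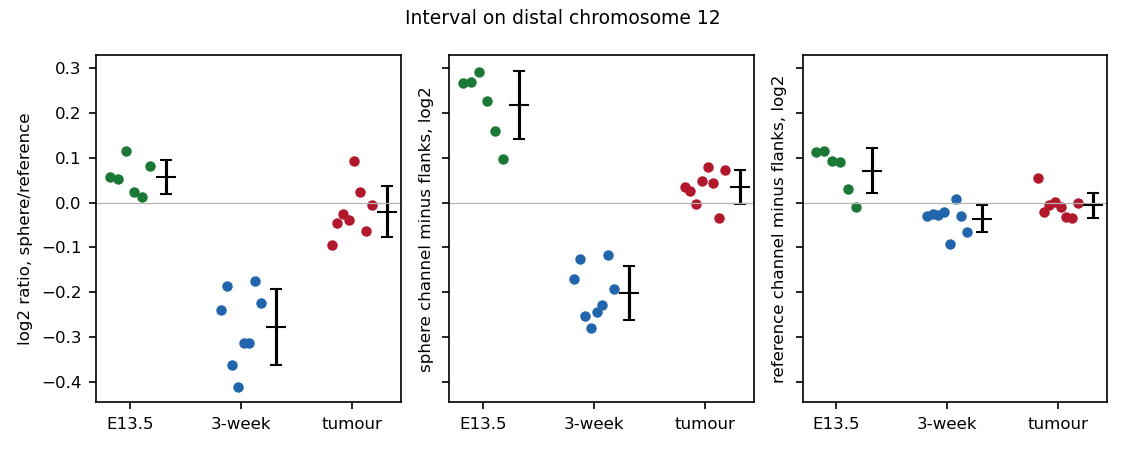
Chromosome 12 from 114670169 to 115126863 in each array of the 3 groups, with mean and SD beside the points: log2 ratio of sphere over reference (left), and the sphere channel (middle) and reference channel (right) in log2 against the flanking probes, each probe centred on its mean over all arrays. All 8 3-week arrays lie below 0 in the ratio (mean -0.28), and tumour and E13.5 means are -0.02 and 0.06.

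Against the reference, X was higher in spheres of the ganglion. The X median was 0.07 ± 0.032 (SD, n = 6) in E13.5 spheres and 0.07 ± 0.027 (SD, n = 8) in 3-week spheres, higher in every array of both groups, and -0.00 ± 0.033 (SD, n = 8) in tumour spheres. Chromosome 11, which carries the mouse counterparts of human 17q, lay at -0.05 ± 0.012 in E13.5 spheres, -0.05 ± 0.016 in 3-week spheres and -0.00 ± 0.013 in tumour spheres. Chromosome 19 lay at -0.02 ± 0.010 in 3-week spheres and 0.01 ± 0.011 in tumour spheres. In exact sign-flip permutation tests 13 of 20 chromosomes differed from 0 in E13.5 spheres, 19 in 3-week spheres and 7 in tumour spheres. With 6 arrays the E13.5 calls sit at the smallest p the test allows (0.031, adjusted p = 0.048), and the count was 0 with any single E13.5 array left out, since 5 arrays cannot pass. The tumour count was 0 with tumour 1, 2, 3, 4, 6, 7 or 8 left out in turn (8 of 20 at an unadjusted p under 0.05 in each case) and 9 without tumour 5. With 7 arrays the smallest p of the sign-flip test is 0.016, against 0.0078 with 8. These 0s come with that coarser p, so they do not show that the calls rest on each array.

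Between tumour and 3-week spheres, both set against spleen, chromosome 11 was higher in tumours by 0.05 (exact permutation test, p = 0.00016, the smallest possible, adjusted p = 0.00078) and chromosome 19 by 0.04 (adjusted p = 0.00078). X was lower in tumours by a difference of -0.08 (adjusted p = 0.0013). Among spheres with a Y signal (5 tumour and 3 3-week arrays) the X difference was -0.05 (exact permutation test, p = 0.071, adjusted p = 0.13), among those without (3 and 5) it was -0.10 (p = 0.018, the smallest possible, adjusted p = 0.054), and permuted within these classes it was -0.07 (adjusted p = 0.0086). Chromosome 3 differed by -0.09 (adjusted p = 0.00078), a size that tumour 5 sets. Without the 2 arrays with a lower chromosome 3 the difference was -0.03 and still passed (exact permutation test, adjusted p = 0.00089). These 4 were among 11 of 20 chromosomes that differed. The trend on probe density was removed for windows only, so chromosome medians were not tested without it in any comparison. In windows of 1 Mb, tumour spheres were lower than 3-week spheres in 468 and higher in 96 of 2531 (limma, adjusted p under 0.05). The lowest were chromosome 3 from 44000001 to 45000000 (difference -0.25, adjusted p = 0.00063, and -0.19 without tumour 5) and chromosome 1 from 149000001 to 150000000 (-0.25, adjusted p = 2.9e-07). Chromosome 2 from 54000001 to 55000000 (-0.24, adjusted p = 1.5e-07) and X from 110000001 to 111000000 (-0.23, adjusted p = 2.4e-07) were also among the 10 lowest, the latter at -0.11 ± 0.059 in tumours and 0.12 in 3-week spheres. The highest were chromosome 15 from 78000001 to 79000000 (0.15, adjusted p = 5.5e-07) and chromosome 4 from 129000001 to 130000000 (0.14, adjusted p = 4.5e-07), with tumours at 0.00 and -0.01 and 3-week spheres at -0.14 and -0.16. With tumour 5 included, whose chromosomes 3 and 1 both lay low, chromosome 3 held 71 of the lower windows, X 70 and chromosome 1 46. Chromosome 11 held 18 of the higher. The count of 564 windows was 254 once a trend on probe density was removed (88 higher and 166 lower). Of these, 151 were among the 564 in the same direction, 133 lower and only 18 of the 96 higher, so most higher windows depended on the trend. The count was 175 in the authors' table (9 and 166) and 574 with the slide as a random block. After normexp correction 152 were higher and 403 lower. Over autosomal windows the sphere channel followed the difference in the ratio with a slope of 0.676 and the reference channel with -0.337.

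Between tumour and E13.5 spheres, chromosome 11 was higher in tumours by 0.05 (exact permutation test, p = 0.00033, the smallest possible, adjusted p = 0.0017) and chromosome 7 by 0.03 (adjusted p = 0.0017). Chromosome 14 differed by -0.03 (adjusted p = 0.0017), chromosome 16 by -0.03 (adjusted p = 0.0017) and X by -0.07 (adjusted p = 0.0044), among 11 of 20 chromosomes. Permuted within arrays with or without a Y signal, the X difference was -0.07 (exact permutation test, adjusted p = 0.016). Tumours were lower in 563 windows and higher in 158. Among the lowest were chromosome 1 from 148000001 to 149000000 (limma, difference -0.28, adjusted p = 9.2e-09), chromosome 7 from 69000001 to 70000000 (-0.27, adjusted p = 2.5e-09) and chromosome 16 from 72000001 to 73000000 (-0.26, adjusted p = 2.9e-09). The highest were chromosome 16 from 8000001 to 9000000 (0.16, adjusted p = 2.1e-07) and chromosome 5 from 144000001 to 145000000 (0.14, adjusted p = 1.1e-07). The window on chromosome 7 lay at -0.24 ± 0.050 in tumours against the spleen reference, and the other 2 lay at -0.09 ± 0.049 and -0.06 ± 0.035 in tumours and at 0.19 and 0.20 in E13.5 spheres. With the scan session as a block 615 windows were called and within the later session 608. No chromosome passed within that session, which holds 2 E13.5 arrays (7 of 20 at an unadjusted p under 0.05). Its 45 splits allow too coarse a p for 7 chromosomes to pass after adjustment. The windows numbered 270 in the authors' table and 428 with the density trend removed (162 higher and 266 lower). Of the 721 called with the trend, 284 stayed called in the same direction (49 higher and 235 lower). The references differ too, spleen for tumour and embryo head for E13.5 spheres. Over autosomal windows the sphere channel followed the difference in the ratio with a slope of 0.902 (0.861 to 0.972 with each array left out) and the reference channel with -0.0777, and within the later session the slopes were 0.701 and -0.289.

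Between spheres of the ganglion at both ages 37 of 2531 windows differed, 18 higher and 19 lower at 3 weeks. The lowest at 3 weeks was chromosome 12 from 115000001 to 116000000 (limma, difference -0.19, adjusted p = 1.9e-07), at -0.07 ± 0.026 (SD, n = 8) in 3-week spheres and 0.12 in E13.5 spheres. Chromosome 11 from 39000001 to 40000000 (-0.14, adjusted p = 0.00016) and chromosome 5 from 12000001 to 13000000 (-0.13, adjusted p = 0.00045) were lower at 3 weeks too. Chromosome 1 from 123000001 to 124000000 (0.13, adjusted p = 0.00031), chromosome 7 from 14000001 to 15000000 (0.12, adjusted p = 0.00021) and chromosome 2 from 22000001 to 23000000 (0.12, adjusted p = 1e-05) were higher. Of 20 chromosomes 9 differed, by at most 0.02 in size, the most marked being chromosome 19 (-0.02, exact permutation test, adjusted p = 0.025). With the scan session as a block and within the later session 11 windows were called, and no chromosome passed within that session (4 at an unadjusted p under 0.05). The 45 splits of that session allow too coarse a p for 4 chromosomes to pass after adjustment. Without E13.5 4 or E13.5 6 the count of chromosomes was 5. The windows split into 27 higher and 15 lower after normexp correction, 23 and 11 under chromosome centring and 22 and 8 in the authors' table. The sphere channel followed the difference in the ratio with a slope of 0.584 (0.508 to 0.647 with each array left out) and the reference channel with -0.339. Within the later session the slopes were 0.404 and -0.465, and the sphere slope ranged from 0.221 to 0.360 with a single E13.5 array, so reference tissue cannot be told apart from stage with these 2 arrays.

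Against their references, E13.5 spheres had 459 higher and 179 lower windows, 3-week spheres 449 and 186, and tumour spheres 118 and 228. With the density trend removed these were 232 and 157, 259 and 179, and 147 and 159, and after normexp correction tumour spheres had 245 and 221. Called both with and without the trend in the same direction were 269 windows in E13.5, 332 in 3-week and 269 in tumour spheres. In E13.5 spheres the highest was chromosome 5 from 12000001 to 13000000 (0.24 ± 0.056, SD, n = 6) and the lowest chromosome 5 from 117000001 to 118000000 (-0.16 ± 0.033). In 3-week spheres the highest was chromosome 13 from 83000001 to 84000000 (0.27 ± 0.015, SD, n = 8) and the lowest chromosome 9 from 46000001 to 47000000 (-0.17 ± 0.014). In tumour spheres the highest was chromosome 6 from 41000001 to 42000000 (0.21 ± 0.024, SD, n = 8), and the lowest were chromosome 3 from 55000001 to 56000000 (-0.24 ± 0.17, and -0.18 without tumour 5) and chromosome 7 from 69000001 to 70000000 (-0.24 ± 0.050). E13.5 and 3-week spheres shared 317 higher windows, where independent lists would share 81.4, and 110 lower ones (13.2). E13.5 and tumour spheres shared 61 higher (21.4) and 7 lower (16.1), and 3-week and tumour spheres 92 higher (20.9) and 27 lower (16.8). Over 2383 autosomal windows, which are not independent replicates, the group means correlated at r = 0.882 between E13.5 and 3-week spheres, 0.443 between 3-week and tumour spheres and 0.234 between E13.5 and tumour spheres, and with the density trend removed at 0.854, 0.584 and 0.373. Windows with at most 45 probes had a median of 0.07 in E13.5 spheres, 0.06 in 3-week spheres and -0.03 in tumour spheres, and windows with at least 89 probes -0.06, -0.05 and 0.01. With the density trend removed 389 windows were called in E13.5 spheres, and the authors' table called 184 in E13.5 and 399 in 3-week spheres.

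**Figure D4:**
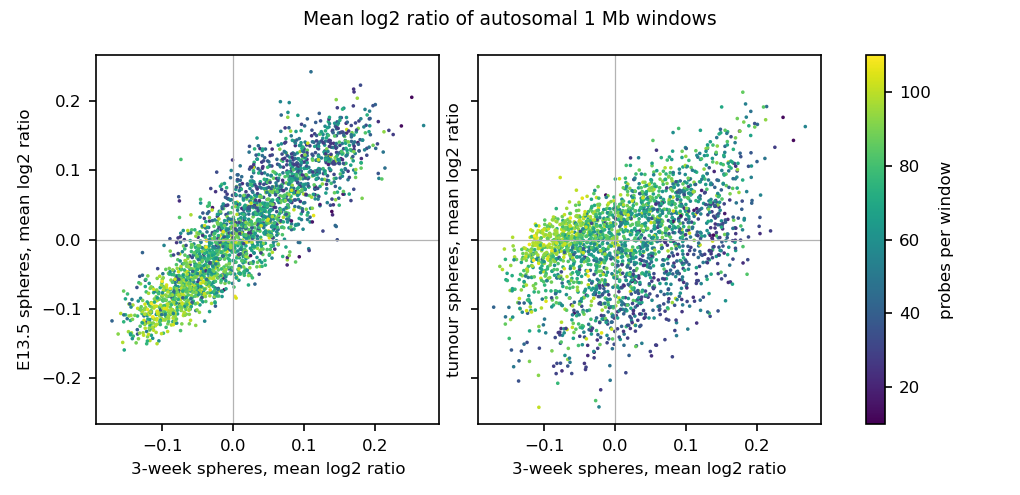
Mean log2 ratio of each autosomal window of 1 Mb in E13.5 spheres (left) and tumour spheres (right) on the y axis against 3-week spheres on the x axis, coloured by the number of probes in the window. The windows follow one line in the left panel (r = 0.882) and scatter more widely in the right panel (r = 0.443), where windows with few probes lie low in tumour spheres.

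The gene lists fixed beforehand moved little, since each member takes the median of its chromosome. Of 72 list tests 20 passed, with a largest mean of 0.05 and a largest difference of 0.05 in size. The list of human 17q genes, which gathers Brca1, Birc5, Ppm1d, Nf1 and 18 others on mouse chromosome 11, was higher in tumour than in 3-week spheres by 0.05 (exact permutation test, adjusted p = 0.004) and than in E13.5 spheres by 0.05 (adjusted p = 0.004). The 17 placed human 11q genes on chromosome 9, among them Atm and Chek1 of the DNA damage response, were higher in tumours than in 3-week spheres by 0.02 (adjusted p = 0.004) and than in E13.5 spheres by 0.02 (adjusted p = 0.03). The human 1p36 genes on chromosome 4, with Chd5 and Kif1b, differed between tumour and 3-week spheres by 0.01 (adjusted p = 0.012) and passed no other test between groups. The list around Mycn on chromosome 12 was lower in 3-week than in E13.5 spheres by a difference of -0.02 (adjusted p = 0.004). The distal chromosome 18 genes lay at -0.03 ± 0.061 (SD, n = 8) in tumours, a mean that tumour 7 sets, and passed only between 3-week and E13.5 spheres (-0.01, adjusted p = 0.026). Neuroblastoma genes differed between tumour and 3-week spheres by 0.010 (adjusted p = 0.008), and cell cycle and tumour suppressor genes by 0.010 (adjusted p = 0.004), the latter also between tumour and E13.5 spheres by 0.0089 (adjusted p = 0.047). PRC2 subunits, members of a repressive chromatin complex, differed between tumour and 3-week spheres by 0.0094 and between tumour and E13.5 spheres by 0.012 (adjusted p = 0.03 for both). Vomeronasal receptor genes differed between tumour and E13.5 spheres by 0.027 (adjusted p = 0.004) and between tumour and 3-week spheres by 0.016 (adjusted p = 0.012). Against the reference, 6 lists passed in 3-week spheres, all with negative means, and 0 in the other groups. In E13.5 spheres even lists at the smallest p of the sign-flip test (0.031) reached only an adjusted p of 0.08. The 0 there is therefore no sign of a difference from 3-week spheres: the human 17q list lay at -0.047 in E13.5 and -0.054 in 3-week spheres. Olfactory receptor, sympathoadrenal, and telomere and chromatin genes passed no test. All these values speak of whole chromosomes, not of the genes named, and 36 tests passed under another centring. The list tests were not rerun with the density trend removed.

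X and Y probes showed the sex of the animals in each channel. In 11 arrays neither channel had a Y signal, with X between -0.12 and -0.01 against the autosomes in the sphere channel, and in 10 both had one, with X between -0.96 and -0.86. Spheres carried a Y signal in 3 E13.5, 3 3-week and 5 tumour arrays. Tumour 7 was the exception: its spheres had a Y level of -0.88, inside the range of the other arrays with Y (-0.89 to -0.70), while its spleen reference lay at -4.66, inside the range of references without Y. Its X level was -0.98 in the spheres and -0.97 in the reference, both at the level of a single X. The labels do not state whether this spleen came from the same animal as the spheres, which bears on every ratio of tumour 7, chromosome 18 included.

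**Figure D5:**
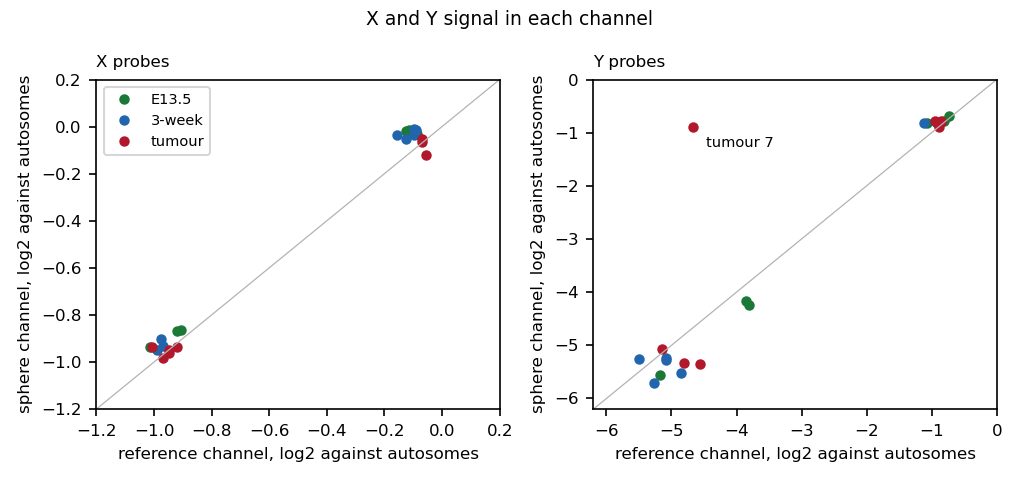
Level of the X probes (left) and Y probes (right), in log2 against the autosomes, in the sphere channel (y axis) against the reference channel (x axis) for each of the 22 arrays, with a line where both are equal. All arrays lie near the line for X, and tumour 7 alone leaves it for Y (sphere -0.88, reference -4.66).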

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

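The tests that weigh explanations and the splits of the arrays were chosen only after the results they measure were seen. The share of autosomal probes in called segments stood apart from the rest of its group in E13.5 2 (3.92%, others up to 0.669%), 3-week 3 (1.72%, others up to 0.383%) and tumour 5 (6.77%, others up to 1.65%). Among chromosome medians, chromosome 3 stood apart in tumour 5 (-0.49) and E13.5 2 (-0.19), chromosome 18 in tumour 7 (-0.18), chromosome 1 in tumour 5 (-0.11) and 3-week 6 (-0.021), and chromosome 2 in E13.5 6 (-0.049). Smaller departures were chromosome 18 in 3-week 2 (-0.025), chromosome 15 in E13.5 2 (0.017), and in tumour 5 chromosomes 2 (0.023), 4 (0.025), 6 (0.034), 12 (0.012), 13 (0.048) and 15 (0.011). Chance alone gives such an array in about 1 in 20 groups of values. The 69 groups examined are not independent, and 8 of the 18 values found are chromosome medians of tumour 5, all centred together with its chromosome 3. That centring moves the other chromosomes up, so it does not give the lower chromosome 1 (-0.11). The groups differed in 564 windows (tumour minus 3-week), 721 (tumour minus E13.5) and 37 (3-week minus E13.5), in 11, 11 and 9 chromosomes, and in noise, by -0.0443 and -0.0331 for tumour against 3-week and E13.5 arrays.

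Over windows, E13.5 and 3-week spheres resembled each other more than tumour spheres. The real split alone among 100 reached each window count (564 against a highest other of 304, 721 against 618, 37 against 4). Within the later scan session, where the last count was 11 in place of 37, the real split was also alone among 45. There the counts were 608 against 148 for tumour minus E13.5 and 11 against 2 for 3-week minus E13.5. Such splits argue against chance only down to 1 of 100 and 1 of 45. They cannot tell the group from the slide, since each slide held arrays of 1 group. The slopes of the channels do not settle whether the reference DNA is the whole origin. The ratio holds both channels, so the 2 slopes of a pair differ by about 1 by construction, and independent variation in either channel moves them. Both tumour contrasts moved more in the sphere channel than in the reference channel. For tumour minus 3-week the sphere slope was 0.676 (0.639 to 0.705 with each array left out) and the reference slope -0.337. For tumour minus E13.5 the sphere slope was 0.902 (0.861 to 0.972), and 0.521 to 0.857 within the later scan session with a single E13.5 array. For 3-week minus E13.5 it was 0.584, but 0.404 within that session and 0.221 to 0.360 there with a single E13.5 array. The reference cannot be told apart in that comparison with 2 E13.5 arrays. The tables argue against the scan session, since E13.5 arrays of the later session correlated over windows at 0.896 with 3-week and 0.220 with tumour spheres. They also argue against a trend on probe density as the whole cause, since with it removed 254 windows were called. Only 151 of the 564 were among them, 18 higher and 133 lower. The group means still correlated at 0.854 between E13.5 and 3-week spheres, against 0.584 and 0.373 with tumours. With the slide, each of 1 group, as a random block, arrays of a slide were not more alike than others of their group (correlation -0.0842). With that block 574, 738 and 42 windows were called. The block cannot show a slide effect that coincides with the group, so such an effect stays open. Passaging and the age and origin of the cells stay open too and were not tested.

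The Y log2 ratio of tumour 7 was 3.35 (other tumours -0.34 to 0.07), on probes used between groups only to split the arrays for X. The tables argue against a different number of X copies in spheres and reference, since the X ratio was -0.018, and against extra Y copies, since the sphere channel lay at -0.88. The X ratio cannot settle whether the sexes differed, since this reference had the level of a single X and no Y signal. Y DNA missing from the spleen reference is a candidate explanation, since the reference lay at -4.66 for Y (arrays without Y -5.50 to -3.81) and at -0.97 for X. Whether that spleen came from another animal was not tested; if it did, each ratio of tumour 7 would compare different animals. No difference that the design names was tested as an explanation.

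The lower interval of chromosome 12 in 3-week spheres (114670169 to 115126863, 37 probes) was found and tested on the same arrays: its mean was -0.28, and exact permutation tests gave p = 0.00016 against tumour and 0.00033 against E13.5 spheres, each the smallest possible (adjusted p = 0.0006 for both). The tables argue against a difference in the spleen DNA, since the reference channel differed by -0.030 (3-week minus tumour) and by -0.11 against the embryo head of E13.5 spheres (adjusted p = 0.001, exact permutation test), where a lower reference raises the ratio, and against the genome-wide profile of ganglion spheres, since the E13.5 mean was 0.057. The scan session bears on that -0.11: E13.5 references lay at 0.090 to 0.115 in the first session and at 0.031 and -0.011 in the later one. The 3-week references, all of the later session, had a mean of -0.036. Between 3-week and tumour spheres the sphere channel differed by -0.24 (exact permutation p = 0.00016), and by -0.17 before each probe was centred on its own mean. Tumour spheres lay below E13.5 spheres too, by -0.077 in the ratio (exact permutation test, adjusted p = 0.021) and -0.18 in the sphere channel (adjusted p = 0.0006). The scan session bears on the E13.5 sphere channel as well, at 0.23 to 0.29 in the first session and 0.16 and 0.097 in the later one. B-lineage cells with a rearranged Igh locus might lower such an interval, but this cannot be told apart here, since the locus was not placed on mm9. Loss of 1 of 2 copies in 35.1% of cells, or of both in 17.6%, would give the mean.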

How the results depend on the processing

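The subsets by scan session, the noisiest arrays, both arrays with a lower chromosome 3, the removal of a density trend, array-specific ratios, the authors' table for segments and chromosomes and the shared segments with an array left out were chosen only after the data were seen. Of 182 values under alternatives other than leaving out an array, 127 kept their direction and their side of the threshold or stayed within 1.5 times; of 198 with an array left out, 179 did. Where no cause is named, the cause was not tested. On the 168932 of 170305 probes well above background on all arrays 570, 725 and 36 windows differed, against 564, 721 and 37 on all probes. The GC corrections and the antigen receptor loci were not run.

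Windows against the reference (E13.5 638, 3-week 635, tumour 346) numbered 1880, 1953 and 1592 with no size minimum and 8, 15 and 8 with a minimum of 0.2, by construction. The authors' table gave 184 for E13.5 and 399 for 3-week spheres, normexp 958 for 3-week spheres, and removal of the density trend 389 for E13.5 spheres. With an array left out they ranged from 575 to 702, 588 to 685 and 315 to 381. Windows that differed (tumour minus 3-week 564, tumour minus E13.5 721, 3-week minus E13.5 37) numbered 1799, 1819 and 514 with no size minimum and 37, 93 and 0 with a minimum of 0.2 (limma; 1863, 1872 and 808 at an unadjusted p under 0.05). They were 175 and 270 for the tumour contrasts in the authors' table and 254 and 428 without the density trend. Called both with and without that trend in the same direction were 151 and 284. The 3-week minus E13.5 count was 11 with the session as a block and 11 in the later session alone. With an array left out they ranged from 490 to 655, 667 to 797 and 31 to 55.

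The share in called segments reversed for tumour minus 3-week spheres with calls from 0.1 (-6.53) and after normexp (-2.20), and passed the threshold with calls from 0.3 (0.918) and in the authors' table (1.45). Tumour minus E13.5 spheres reversed with calls from 0.1 (-9.33) and with array-specific ratios (-0.017). The 3-week minus E13.5 difference reversed with calls from 0.3 (0.0015), after normexp (2.78), in the later session (0.292) and without both arrays with a lower chromosome 3 (0.129). With an array left out the 3 differences ranged from 0.55 to 1.48, 0.0616 to 1.41 and -0.686 to 0.129; tumour minus 3-week passed the threshold without 3-week 3 (1.48).

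Chromosomes off 0 in E13.5 spheres (13) numbered 0 after normexp, under chromosome centring, with chromosome means and in the authors' table (12, 12, 3 and 8 at an unadjusted p under 0.05, exact permutation tests). With 6 arrays, 13 chromosomes at the smallest p (0.031) gave an adjusted p of 0.048, and 12 at that p cannot pass. The unadjusted counts, not these 0s, therefore show how far the result moved. Leaving out both arrays with a lower chromosome 3, or any array, also gave 0 (0 to 0), since 5 arrays cannot pass. Tumour spheres (7) gave 0 after normexp (6 unadjusted) and 0 to 9 with an array left out, 3-week spheres (19) 16 to 19. Leaving out an array raises the smallest p from 0.0078 to 0.016, which lowers the tumour count by itself. Tumour minus 3-week (11) gave 7 in the authors' table and 11 to 14 with an array left out. Tumour minus E13.5 (11) gave 7 with means, 4 in the authors' table, 0 in the later session (7 unadjusted) and 8 to 13. For 3-week minus E13.5 (9) the counts were 0 with means (3 unadjusted), 0 in the later session (4 unadjusted) and 5 to 11. The later session allows only 45 splits, so its smallest p passes only when more chromosomes than these share it. The list tests that passed (20) numbered 36 under chromosome centring. Shared focal segments (E13.5 4, 3-week 4, tumour 22) numbered 0 and 3 for E13.5 and tumour spheres with calls from 0.3, and 0, 1 and 11 with a penalty of 8. With an array left out they ranged from 3 to 4, 2 to 4 and 14 to 21, lowest without 3-week 5 and without tumour 3 for the latter groups. Array-specific ratios gave 0, 1 and 0 by construction, since they take out what most arrays of a group share, and say nothing of stability.

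The replicate numbers do not pair the samples: same-numbered arrays correlated from -0.55 to 0.32, and 0 correlated best with their own number. With the replicate number as a block 561, 715 and 34 windows differed, the shares differed by 1.29, 1.104 and -0.376, and 11, 0 and 0 chromosomes passed (7 and 5 unadjusted for the latter). With the 6 pairs of those comparisons the smallest p is 0.031, at which 7 or 5 chromosomes cannot pass. No other call changed.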

Other observations

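The regions here were chosen after their values were seen. Along chromosome 18 of tumour 7, whose median was -0.18, the segments past 0.2 had means from -0.23 to -0.34, and the one at the distal end (85630829 to 90686349, 242 probes) lay at -0.30. Against the median of the other tumour arrays, segments were called from 69759358 to 73778302 (-0.22) and from 85156912 to 90744509 (-0.22). On chromosome 1 the window from 26000001 to 27000000 was lower in all 8 tumours (-0.19 ± 0.061, SD, n = 8), and called segments over it lay in tumour 5 from 24315899 to 30404589 (-0.24), in tumour 3 from 25937029 to 30404589 (-0.25) and in tumour 7 from 25806903 to 30839307 (-0.21), and tumour 5 had another from 60882242 to 63976554 (-0.27). Against the median of the other tumour arrays, which takes out what tumours share, no segment was called on chromosome 1. A call needs a mean of 0.2 in size, so this cannot detect a shift such as the chromosome 1 median of tumour 5 (-0.11).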
